A study of Homo sapiens with 48 samples.

How the data were processed

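RNA sequencing of the human diffuse large B-cell lymphoma line U2932 was taken from the deposited files of 48 libraries, made from poly(A) RNA with a directional library kit per the labels. Groups follow the labels: WT and KLHL6-KO cells at 0, 3, 8 and 12 h of coculture with OP9-DLL1 (24 libraries), WT, KLHL6-KO, NOTCH2-KO and DKO xenografts (12) and xenografts of cells expressing NOTCH2(WT) or its variants S2156A, R2400* and Q2140* (12). All tumours grew in NSG mice given CHOP (prednisone, vincristine, doxorubicin and cyclophosphamide) and were collected at 1 cm3 per the labels. Each of the 16 groups holds 3 libraries, and no library was left out.

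The authors aligned reads with STAR to GRCh38, handled alignments with SAMtools and normalised with DESeq2, per the submitters' processing notes. Tool versions, the read counter and the annotation used are not given in the sources used here. The deposited values are normalised signal, gene counts divided by a size factor for each library, and 100% of values in each library are whole multiples of 1 step within 0.02 steps. The reads of each library were recovered by dividing by that step. Depth was 11.1 to 17.4 M reads in coculture (median 12.5), 3.71 to 15.2 M in the knockout tumours (median 13.7, labelled DKO replicate 3 lowest) and 12.7 to 17.1 M in the mutant tumours (median 14). Between replicates the chi-square over its degrees of freedom ran from 1.37 to 65.8, where 1 is counting noise alone, so replicates spread more than depth accounts for. No 2 libraries were identical. The authors normalised the 3 series separately, so levels are not compared between them.

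The coculture files have 60558 gene rows with Ensembl identifiers (26651 at 0 in all libraries). The knockout files have 14026 rows and the mutant files have 34870, named by gene symbol. Rows named as dates by a spreadsheet (16 and 26, at most 0.252% of reads) and 1 row named 0 in each set of tumour files were left out. Names were matched to GENCODE 29 on GRCh38, which may differ from the annotation the authors used. For the knockouts 12077 names were current, 569 matched as older names and 1360 had no match, and for the mutants these were 23328, 1126 and 10375. The knockout files hold no row with fewer than 121 reads in total, so genes of low expression are missing there.

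Each comparison was tested with limma 3.58.1 (R 4.3.3, empirical Bayes with trend and robust settings) on log2(deposited value + 2), with 1 coefficient per group over all libraries of the experiment. Genes with a value of at least 10 in at least 3 libraries were kept, 15032 in coculture, 14005 in the knockout tumours and 15354 in the mutant tumours. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The design, written before the values were known, had assumed edgeR quasi-likelihood on counts. Because the deposited values are normalised, limma was used instead and edgeR became an alternative. The 23 comparisons were each coculture time against 0 h within genotype, KLHL6-KO against WT at each time, the joint test of genotype by time, the tumour comparisons between knockout groups with the interaction of KLHL6 and NOTCH2, and all pairs of the mutants. Each SE is that of the limma coefficient, and for genotype by time that of the mean of the 3 terms.

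The 26 gene lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. They cover NOTCH targets, the NOTCH pathway, ribosome biogenesis and MYC, cell cycle, NF-kB, B-cell receptor signalling, B-cell identity, plasma cells, the germinal centre, MHC class II, interferon, cholesterol, hypoxia and glycolysis, p53 targets, the unfolded protein response, immediate-early genes, the BCL2 family, drug response, migration and adhesion, mitochondrial transcripts, and markers of stroma, macrophages, endothelium, T and NK cells, adipocytes and red cells. Lists with fewer than 3 measured members were not tested, which left out adipocytes and red cells everywhere and macrophages, endothelium and T and NK cells in coculture. Members called are counted over all genes and with the adjustment over the list alone. Named genes are KLHL6, NOTCH2, the NOTCH targets, the 8 largest rises and 8 largest falls among called genes at a mean of at least 2 CPM whose groups do not overlap, and the 4 smallest p of each called list. Immunoglobulin and T-cell receptor segments were left out, as were sex-linked marker genes. The values of some genes named by this rule are not reported here.

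Correlations of log2 changes between comparisons used genes tested in both. For comparisons against the same NOTCH2(WT) libraries the correlation was set beside 50 simulations without effects. The pipeline was tested on simulated data with 200 changed genes. For WT cells at 3 h it called 85.1% of genes changed 1.5-fold, 97.0% at 2-fold and 100% at 4-fold, and for KLHL6-KO against WT at 12 h 86.6, 97.0 and 100%. For labelled KLHL6-KO against WT tumours these were 62.7, 95.5 and 100%, for S2156A 73.1, 97.0 and 100%, for genotype by time 74.6, 92.5 and 98.5%, and for KLHL6 by NOTCH2 34.3, 71.6 and 95.5%. The share of false calls was 5.53, 6.44, 4.97, 6.25, 9.23 and 1.47% in the same order.

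Alternatives were each library left out, the libraries of the 2 groups alone, the replicate number as a block, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads (Wald test, and likelihood ratio test for genotype by time), TMM scaling, pseudocounts of 0.5 and 8, no filter, genes of at least 2 CPM for correlations, and libraries that stood apart left out. Those libraries were coculture WT 12 h replicate 1, tumour WT replicate 1 and tumour DKO replicate 3. Files were read with the R package data.table, release 1.17.8. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.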

Results

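RNA was measured in the human diffuse large B-cell lymphoma line U2932 in 3 experiments of 48 libraries, with n = 3 libraries in each of 16 groups. In the coculture experiment, WT and KLHL6-KO cells were collected after 0, 3, 8 and 12 h on OP9-DLL1, a stromal line that presents the NOTCH ligand DLL1 (24 libraries). The knockout tumours were xenografts of WT, KLHL6-KO, NOTCH2-KO and DKO cells (KLHL6 and NOTCH2) in NSG mice treated with CHOP (12 libraries). The mutant tumours came from cells stably expressing NOTCH2(WT) or 1 of its variants S2156A, R2400* and Q2140* under the same treatment (12 libraries). Depth was 11.1 to 17.4 M reads in coculture (median 12.5), 3.71 to 15.2 M in the knockout tumours (median 13.7) and 12.7 to 17.1 M in the mutant tumours (median 14). Levels are normalised counts, mean ± SD of 3 libraries. Changes are log2 ± SE from limma with the Benjamini-Hochberg adjusted p, 3 libraries against 3. Whether the replicates are separate cultures or animals is not stated beyond their labels, so each p-value measures the spread between these samples.

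KLHL6 (ENSG00000172578, chromosome 3, 183487531 to 183555689, GRCh38, GENCODE 29), which encodes an adaptor of a ubiquitin ligase, was lower in KLHL6-KO than in WT cells at every time of coculture. At 0 h it was at 2381 ± 177 against 5389 ± 747 counts, a log2 change of -1.17 ± 0.12 (adjusted p = 1.8e-06). The change was -0.63 ± 0.12 at 3 h (2866 ± 214 against 4434 ± 90.7, adjusted p = 0.0031), -1.15 ± 0.12 at 8 h (2105 ± 321 against 4694 ± 902, adjusted p = 9.8e-06) and -1.12 ± 0.12 at 12 h (2473 ± 161 against 5399 ± 540.0, adjusted p = 1.2e-05). Coculture changes of KLHL6 were not called with all libraries. At 3 h they were -0.27 ± 0.12 in WT cells (adjusted p = 0.072) and 0.27 ± 0.12 in KLHL6-KO cells (adjusted p = 0.1), both called with the libraries of these groups alone (adjusted p = 0.014 and 0.0020). In WT cells the fall was called at 3 h without WT 0 h replicate 3 (adjusted p = 0.026) and at 8 h without WT 8 h replicate 1 (0.0091). The interaction of genotype and time for KLHL6 (adjusted p = 0.098) was called without KLHL6-KO 8 h replicate 1 (0.038) or WT 8 h replicate 1 (0.035). NOTCH2 (ENSG00000134250, chromosome 1, 119911553 to 120069626) fell in WT cells on OP9-DLL1 from 598 ± 149.6 counts at 0 h to 238 ± 35.3 at 8 h (-1.30 ± 0.18, adjusted p = 4.2e-06) and 325 ± 27 at 12 h (-0.85 ± 0.18, adjusted p = 5.2e-04). In KLHL6-KO cells it was not called (8 h, -0.34 ± 0.18, adjusted p = 0.14, and 0.0088 with the libraries of these groups alone). The interaction of genotype and time was at the threshold (mean term 0.63 ± 0.20, adjusted p = 0.048). That call was lost without the filter (adjusted p = 0.12), with edgeR (0.055) and without any 1 library (0.054 to 0.11) other than WT 0 h replicate 3, WT 8 h replicate 1, KLHL6-KO 0 h replicate 1 or KLHL6-KO 3 h and 12 h replicates 1 and 3. Before coculture NOTCH2 was lower in KLHL6-KO cells (373 ± 60.7 against 598 ± 149.6, -0.66 ± 0.18, adjusted p = 0.01), a call lost without WT 0 h replicate 1 (adjusted p = 0.063) or without KLHL6-KO 0 h replicate 3 (adjusted p = 0.055).

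**Figure D1:**
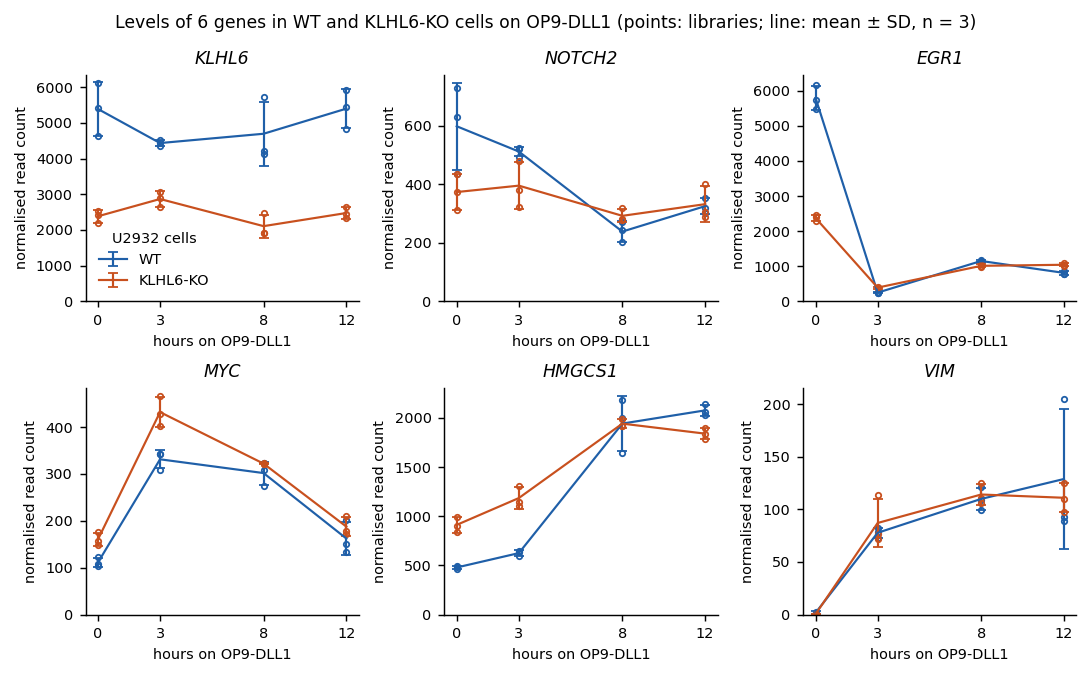
KLHL6, NOTCH2, EGR1, MYC, HMGCS1 and VIM in WT and KLHL6-KO U2932 cells at 0, 3, 8 and 12 h on OP9-DLL1. Points are libraries, lines join means, bars are SD, n = 3 per group. EGR1 in WT cells was at 5799 ± 345 counts at 0 h and 246 ± 12.5 at 3 h.

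In WT cells, immediate-early transcripts, which follow receptor and stress signals, fell over the first 3 h on OP9-DLL1. MYC and the machinery of ribosome assembly rose. EGR1 fell to 246 ± 12.5 counts from 5799 ± 345 (-4.55 ± 0.06, adjusted p = 9.1e-35), with CD69 (-3.64 ± 0.13, 2.1e-21) and FOS (-2.64 ± 0.23, 1.2e-11). MYC rose from 111 ± 9.92 to 331 ± 19.6 counts (1.56 ± 0.11, adjusted p = 5.9e-14), with the ribosome factors PPAN (1.34 ± 0.08, 4.7e-16) and GRWD1 (1.26 ± 0.06, 1.1e-17) and the MYC-driven microRNA host MIR17HG (2.44 ± 0.10, 2.2e-19). Of 12 measured NOTCH targets 4 rose and 5 fell (4 and 5 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.67). Lower members included the feedback inhibitor NRARP (-1.24 ± 0.27, 2.2e-04), the repressor HEY2 (-1.38 ± 0.18, 8.3e-08), CR2 (-1.10 ± 0.22, 5.6e-05) and IL2RA (-1.97 ± 0.38, 3.7e-05), and HES1 was not called (-0.13 ± 0.10, adjusted p = 0.27). The ribosome biogenesis and MYC list was raised. Of 28 ribosome and MYC genes 25 were higher and 0 lower (25 and 0 adjusted over the list alone, camera adjusted p = 7.9e-16, adjusted p = 0.054 with an estimated correlation). Hypoxia and glycolysis genes, among them PFKFB4 (-2.36 ± 0.22, 1.2e-08) and HILPDA (-3.15 ± 0.27, 2.7e-08), were lowered. Of 20 hypoxia and glycolysis genes 0 were higher and 11 lower (0 and 11 adjusted over the list alone, camera adjusted p = 1.7e-04, adjusted p = 0.44 with an estimated correlation). Immediate-early genes were lowered too. Of 21 immediate-early genes 5 were higher and 12 lower (5 and 13 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.34 with an estimated correlation). That call was lost with the libraries of these groups alone (adjusted p = 0.096). VIM, a stromal marker close to absence in these B cells at 0 h, went from 1.59 ± 1.46 to 77.7 ± 4.86 counts over the same interval. Limma called 8234 of 15032 genes (4084 higher, 4150 lower, Benjamini-Hochberg adjusted p < 0.05), 475 and 957 of them by at least 2-fold.

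By 8 h, sterol synthesis genes had risen in WT cells, and unfolded protein response genes had fallen. HMGCS1 (2.01 ± 0.08, 1.1e-20) and SQLE (1.60 ± 0.07, 8.5e-19) rose, both of them targets of the sterol-sensing SREBP factors. Of 21 sterol genes 19 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 5.8e-17). CHAC1 (-4.08 ± 0.44, 1.9e-07), ATF3 (-2.78 ± 0.24, 7.9e-12), DDIT3 (-1.83 ± 0.13, 1.2e-13) and TRIB3 (-1.62 ± 0.08, 6.8e-18), which respond to amino acid shortage and endoplasmic reticulum stress, fell. Of 20 unfolded protein response genes 1 was higher and 12 lower (1 and 12 adjusted over the list alone, camera adjusted p = 2.5e-04, adjusted p = 0.054 with an estimated correlation). MYC stayed up (1.43 ± 0.11, adjusted p = 6.3e-13) with the ribosome list. Among ribosome and MYC genes 28 of 28 were higher and 0 lower (28 and 0 adjusted over the list alone, camera adjusted p = 6.9e-19). HES1 rose (448 ± 15.5 against 354 ± 35, 0.34 ± 0.10, adjusted p = 0.0043) while NRARP (-1.62 ± 0.27, 5.0e-06) and HEY2 (-1.56 ± 0.18, 8.9e-09) remained lower. Of the 12 NOTCH targets 5 rose and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.70). VIM was at 109.9 ± 10.6 counts. The test called 8446 genes (4210 higher, 4236 lower), and the same 3 libraries at 0 h serve every time point of WT cells.

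At 12 h the sterol rise persisted in WT cells, with SQLE (1.55 ± 0.07, 8.8e-19). Among sterol genes 20 of 21 were higher and 0 lower (21 and 0 adjusted over the list alone, camera adjusted p = 1.3e-20). The NOTCH target SEMA7A (1.05 ± 0.10, 1.7e-10) had now risen, from 371 ± 6.55 to 773 ± 25.3 counts, whereas HEY2 (-1.15 ± 0.18, 3.1e-06), IL2RA (-1.47 ± 0.38, 0.0014) and CR2 (-1.04 ± 0.22, 1.4e-04) stayed lower (4 NOTCH targets higher and 5 lower, camera adjusted p = 0.67). Ribosome genes remained raised (28 of 28 higher and 0 lower, 28 and 0 adjusted over the list alone, adjusted p = 7.2e-17) and interferon genes were lowered. Of 16 interferon genes 1 was higher and 9 lower (1 and 9 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.068 with an estimated correlation). The stromal transcripts COL1A2 and COL6A2 were at 0 in all 3 libraries at 0 h and at 25.2 ± 17.5 and 14.7 ± 12.6 counts at 12 h. The stroma list was raised (8 of 15 higher and 0 lower, 8 and 0 adjusted over the list alone, adjusted p = 0.011, adjusted p = 0.44 with an estimated correlation), a call lost without WT 12 h replicate 1 (adjusted p = 0.066) and with the libraries of these groups alone (0.17). Mitochondrially encoded transcripts were raised as well (13 of 13 higher and 0 lower, 13 and 0 adjusted over the list alone, adjusted p = 3.1e-04, adjusted p = 0.48 with an estimated correlation), with MT-ND6 (1.91 ± 0.28, 2.2e-05). The mitochondrial share of counts was 16.2 ± 6.53% at 12 h against 9.64 ± 0.452% at 0 h, and replicate 1 at 12 h held 23.2%. The test called 7963 genes (4073 higher, 3890 lower).

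In KLHL6-KO cells on OP9-DLL1 NF-kB genes were higher than at 0 h from 3 h on. The activation marker CD83 (1.40 ± 0.08, 5.2e-15) and the NF-kB inhibitor NFKBIE (0.90 ± 0.08, 2.6e-10) rose at 3 h. Of 23 NF-kB genes 13 were higher and 4 lower (13 and 5 adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.11 with an estimated correlation). At 8 h CD83 (1.43 ± 0.08, 1.6e-15), NFKBIA (1.14 ± 0.08, 2.2e-13) and TNFAIP3 (1.12 ± 0.09, 1.7e-12) were higher (15 of 23 higher and 3 lower, 16 and 3 adjusted over the list alone, adjusted p = 3.7e-06), and at 12 h NFKBIE (1.43 ± 0.08, 2.2e-15), TNFAIP3 (1.37 ± 0.09, 7.2e-15) and TRAF1 (1.08 ± 0.07, 2.9e-15). Among NF-kB genes 15 of 23 were higher and 4 lower (15 and 4 adjusted over the list alone, camera adjusted p = 7.5e-08). Among NOTCH targets SEMA7A rose at each time, to 1032 ± 86.9 counts at 12 h (1.74 ± 0.10, adjusted p = 2.5e-15), and HES1 rose at 8 h (0.60 ± 0.10, adjusted p = 1.4e-05) and at 12 h (0.65 ± 0.10, adjusted p = 3.2e-06), while DTX1 (-0.50 ± 0.05, 2.8e-10) and HES6 (-0.62 ± 0.11, 1.9e-05) fell by 12 h. The receptor and ligand list of the NOTCH pathway was raised at 3 h (8 of 25 higher and 4 lower, 8 and 4 adjusted over the list alone, adjusted p = 0.048, adjusted p = 0.32 with an estimated correlation), a call lost without KLHL6-KO 3 h replicate 1 (adjusted p = 0.093) or 0 h replicate 2 or 3 (adjusted p = 0.056 and 0.071), with the libraries of these groups alone (0.074), with TMM scaling (0.075) and with a pseudocount of 8 (0.064). In that list DLL1, the ligand carried by the OP9 cells, was at 0 in all 3 libraries at 0 h and at 17 ± 8.12 counts at 3 h, and FBXW7 (0.71 ± 0.06, 7.6e-12) and MAML1 (0.67 ± 0.08, 1.9e-08) rose. VIM was at 87 ± 23.2 counts at 3 h against 0.326 ± 0.565 at 0 h.

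Stress and sterol genes moved in KLHL6-KO cells as well. ATF3 (-2.81 ± 0.24, 1.9e-11), TRIB3 (-1.40 ± 0.08, 8.3e-16) and ATF4 (-0.72 ± 0.05, 1.1e-12) fell at 8 h. Among unfolded protein response genes 0 of 20 were higher and 17 lower (0 and 18 adjusted over the list alone, camera adjusted p = 1.2e-13). HMGCS1 (1.09 ± 0.08, 1.4e-13) rose. Of 21 sterol genes 16 were higher and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 8.7e-13). Hypoxia genes fell at 8 h, among them BNIP3 (-1.37 ± 0.10, 3.5e-13) and P4HA1 (-1.01 ± 0.10, 7.3e-10). Among hypoxia and glycolysis genes 1 of 20 was higher and 15 lower (1 and 16 adjusted over the list alone, camera adjusted p = 6.6e-09, adjusted p = 0.13 with an estimated correlation). At 12 h MHC class II genes had risen, with HLA-DQB1 (0.95 ± 0.07, 8.5e-14) and HLA-DRB1 (0.50 ± 0.06, 9.8e-09). Of 14 MHC class II genes 9 were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 4.1e-06, adjusted p = 0.055 with an estimated correlation). EGR2 (1.88 ± 0.14, 1.8e-12) had risen although EGR1 (-1.19 ± 0.06, 8.4e-17) was lower. Among immediate-early genes 13 of 21 were higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 5.8e-04, adjusted p = 0.055 with an estimated correlation). The stroma list was raised beside these (10 of 15 higher and 0 lower, 11 and 0 adjusted over the list alone, adjusted p = 8.5e-05, adjusted p = 0.12 with an estimated correlation), COL1A2 being at 0 in all 3 libraries at 0 h and at 15.6 ± 6.43 counts at 12 h, and the mitochondrial share was 15.2 ± 2.5% at 12 h. The test called 5873 genes at 3 h (2941 of them lower), 5675 at 8 h (2879 and 2796) and 6089 at 12 h (3090 and 2999).

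WT and KLHL6-KO cells shared much of the change from 0 h on OP9-DLL1. At 3 h 2482 genes were higher in both genotypes (796.2 by chance) and 2529 lower in both (812.3 by chance), and at 12 h 2425 were higher in both (835.8 by chance) and 2303 lower in both (776.4 by chance). The log2 changes of the genotypes correlated across 15025 genes with Pearson r = 0.804 at 3 h, 0.789 at 8 h and 0.792 at 12 h. Genes are not independent replicates, so no p-value is attached to these correlations.

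Before coculture, KLHL6-KO cells already held more sterol and ribosome transcripts and fewer immediate-early and MHC class II transcripts than WT cells. HMGCS1 (0.92 ± 0.08, 7.9e-11) was higher. Among sterol genes 18 of 21 were higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 1.9e-18). PPAN (0.72 ± 0.08, 2.5e-08) and MYC (0.52 ± 0.11, 6.4e-04) were higher too. Of 28 ribosome and MYC genes 22 were higher and 0 lower (24 and 0 adjusted over the list alone, camera adjusted p = 1.6e-16). EGR1 (-1.29 ± 0.06, 1.6e-16) and IER2 (-1.01 ± 0.06, 2.7e-13) were lower. Of 21 immediate-early genes 3 were higher and 11 lower (4 and 12 adjusted over the list alone, camera adjusted p = 6.2e-05). HLA-DOA (-0.56 ± 0.06, 3.3e-08) and HLA-DMB (-0.43 ± 0.06, 7.0e-06) were lower as well. Among MHC class II genes 0 of 14 were higher and 11 lower (0 and 11 adjusted over the list alone, camera adjusted p = 3.5e-08). Of the NOTCH targets NRARP (-1.21 ± 0.27, 0.0011) was lower and DTX1 (0.30 ± 0.05, 2.1e-05) higher, and HES7, an oscillating NOTCH repressor, was at 13.8 ± 4.85 against 59.1 ± 16.1 counts (-1.97 ± 0.34, adjusted p = 5.8e-05). The phosphatase PTPN6 (-0.81 ± 0.07, 8.5e-11), which restrains the B-cell receptor, and PRKCB (-0.66 ± 0.08, 1.1e-06) were lower. Of 23 B-cell receptor genes 3 were higher and 6 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.019). That call was lost with the libraries of these groups alone (adjusted p = 0.052). Plasma-cell genes such as XBP1 (0.30 ± 0.05, 1.1e-04) were higher although SDC1 (-1.43 ± 0.33, 0.0014) was lower. Of 15 plasma-cell genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.013). HSPA5 (0.51 ± 0.05, 1.3e-08) and CALR (0.60 ± 0.08, 2.1e-06) were higher. Of 20 unfolded protein response genes 8 were higher and 3 lower (9 and 3 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.2 with an estimated correlation). With the libraries of these groups alone this call was lost (adjusted p = 0.11). Limma called 3927 genes (2055 higher, 1872 lower), 59 and 225 of them by at least 2-fold.

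After 3 h on OP9-DLL1, KLHL6-KO cells exceeded WT cells in NF-kB and immediate-early genes. CCL3 (2.02 ± 0.27, 1.6e-06), a chemokine of activated B cells, and NFKBIE (0.85 ± 0.08, 1.1e-08) were higher. Of 23 NF-kB genes 10 were higher and 1 lower (11 and 2 adjusted over the list alone, camera adjusted p = 3.5e-06). EGR2 (1.72 ± 0.14, 2.7e-10), CD69 (1.42 ± 0.13, 1.5e-09) and EGR1 (0.66 ± 0.06, 4.3e-09) were higher too. Among immediate-early genes 8 of 21 were higher and 3 lower (10 and 3 adjusted over the list alone, camera adjusted p = 1.4e-05). The sterol genes SQLE (0.99 ± 0.07, 5.2e-12) and HMGCS1 (0.92 ± 0.08, 1.3e-10) remained higher. Of 21 sterol genes 19 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 3.7e-44). HLA-DMB (-0.63 ± 0.06, 1.6e-08) and HLA-DPB1 (-0.42 ± 0.05, 5.4e-07) remained lower. Of 14 MHC class II genes 0 were higher and 10 lower (0 and 11 adjusted over the list alone, camera adjusted p = 1.0e-12). Of 12 NOTCH targets 3 were higher and 0 lower (3 and 0 adjusted over the list alone), and the list was called higher (camera adjusted p = 0.016), led by SEMA7A (732 ± 74.3 against 377 ± 65.6, 0.96 ± 0.10, adjusted p = 2.2e-08). PRDM1 (0.76 ± 0.15, 8.5e-04) and ELL2 (0.55 ± 0.07, 2.9e-06), genes of plasma-cell differentiation, were higher. Among plasma-cell genes 4 of 15 were higher and 1 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.0025). The test called 1175 genes (574 higher, 601 lower), 2074 with the libraries of these groups alone, and 647 to 734 without WT 3 h replicate 2 (647), WT replicate 1 (683), KLHL6-KO replicate 2 (724) or KLHL6-KO replicate 3 (734). With the replicate number as a block it called 1814.

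At 8 h the NF-kB excess of KLHL6-KO cells held, with CCL3 (1.72 ± 0.27, 5.4e-05) and CCL22 (0.73 ± 0.13, 3.2e-04). Among NF-kB genes 10 of 23 were higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 1.3e-05). IL6R (1.82 ± 0.34, 6.2e-04) and SEMA7A (0.50 ± 0.10, 0.0013) were higher among NOTCH targets (3 higher and 0 lower in the list, camera adjusted p = 0.095, and 0.018 without KLHL6-KO 8 h replicate 1). The germinal-centre repressor BCL6 (-0.37 ± 0.07, 3.5e-04) was lower. Of 13 germinal-centre genes 1 was higher and 4 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.0045, adjusted p = 0.11 with an estimated correlation). Hypoxia genes were lower with ANKRD37 (-0.73 ± 0.11, 3.6e-05) and P4HA1 (-0.62 ± 0.10, 1.1e-04). Of 20 hypoxia and glycolysis genes 0 were higher and 12 lower (0 and 18 adjusted over the list alone, camera adjusted p = 2.0e-20). The test called 652 genes (303 higher, 349 lower), 1027 with the replicate number as a block, 381 without KLHL6-KO 8 h replicate 3 and 407 without KLHL6-KO 8 h replicate 1.

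At 12 h KLHL6-KO cells carried more of the plasma-cell regulators PRDM1 (0.97 ± 0.15, 5.6e-05), IRF4 (0.50 ± 0.06, 2.4e-06) and ELL2 (0.75 ± 0.07, 2.2e-08) and less BCL6 (-0.63 ± 0.07, 3.7e-08) and CD22 (-0.36 ± 0.06, 1.6e-04) than WT cells. CCL22 (1.00 ± 0.13, 2.3e-06), NFKBIA (0.75 ± 0.08, 8.3e-08) and CD83 (0.56 ± 0.08, 1.2e-05) were higher. Of 23 NF-kB genes 14 were higher and 1 lower (15 and 1 adjusted over the list alone, camera adjusted p = 2.7e-18). EGR2 (0.91 ± 0.14, 7.8e-05) and CD69 (0.89 ± 0.13, 2.2e-05) were higher too. Of 21 immediate-early genes 5 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 1.1e-05). B-cell identity genes were lower as a list. Of 20 B-cell identity genes 0 were higher and 3 lower (0 and 13 adjusted over the list alone, camera adjusted p = 3.1e-05). The germinal-centre list was lower too. Among germinal-centre genes 1 of 13 was higher and 4 lower (1 and 7 adjusted over the list alone, camera adjusted p = 6.6e-05). No NOTCH target apart from SEMA7A was called, and that call (0.41 ± 0.10, adjusted p = 0.01) was lost without KLHL6-KO 12 h replicate 1 (adjusted p = 0.075) or WT 12 h replicate 3 (adjusted p = 0.051). The test called 510 genes (210 higher, 300 lower), 784 with the replicate number as a block and 282 without KLHL6-KO 12 h replicate 3.

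The response to coculture itself differed between the genotypes, in sterol, ribosome, immediate-early and NF-kB genes among others. EGR1 fell less in KLHL6-KO than in WT cells, by a difference of 1.94, 1.10 and 1.65 on the log2 scale at 3, 8 and 12 h (mean 1.57 ± 0.07, adjusted p = 5.4e-17). CD69 (1.74 ± 0.15, 1.4e-09) and FOS (1.51 ± 0.27, 5.6e-04) also had positive terms. Among immediate-early genes 12 of 21 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 1.8e-10). NFKBIE (0.87 ± 0.10, 6.3e-07) and TRAF1 (0.76 ± 0.08, 1.6e-07) had larger responses in KLHL6-KO cells (14 of 23 higher and 2 lower, 17 and 2 adjusted over the list alone, adjusted p = 2.6e-09), as had STAT5A (1.67 ± 0.17, 2.2e-07) and PTPN6 (0.90 ± 0.08, 3.3e-10). HMGCS1 (-0.67 ± 0.09, 3.5e-10) and PPAN (-0.60 ± 0.09, 1.9e-04) had negative mean terms, that of HMGCS1 from 8 and 12 h (-0.915 and -1.10, against -0.00603 at 3 h) (1 of 21 higher and 18 lower, 1 and 19 adjusted over the list alone, adjusted p = 5.2e-12 for sterols, and for ribosome genes 0 of 28 higher and 15 lower, 0 and 20 adjusted over the list alone, adjusted p = 4.0e-12). Of 12 NOTCH targets 4 had positive mean terms, IL6R (1.77 ± 0.39, 0.0078), NRARP (1.21 ± 0.31, 0.029), SEMA7A (0.90 ± 0.11, 2.6e-06) and HEY2 (0.74 ± 0.21, 0.024), and 1 a negative term, DTX1 (-0.37 ± 0.06, 1.8e-04) (6 and 1 adjusted over the list alone), with the list as a whole not called (camera adjusted p = 0.058). Calls were lost for IL6R without KLHL6-KO 0 h replicate 3 (adjusted p = 0.0502), for HEY2 without KLHL6-KO 0 h replicate 2 (0.071) or 3 (0.057), 8 h replicate 3 (0.058), WT 8 h replicate 1 (0.054) or the filter (0.052), and for NRARP without KLHL6-KO 0 h replicate 2 (0.099) or 3 (0.060), 3 h replicate 3 (0.056), WT 0 h replicate 1 (0.081) or 2 (0.086), WT 3 h replicate 3 (0.059) or the filter (0.060). The list was called with TMM scaling (adjusted p = 0.047), with a pseudocount of 8 (0.040), and without KLHL6-KO 0 h replicate 3 (adjusted p = 0.024), 3 h replicate 1 (0.049), 8 h replicate 1 (0.031) or 12 h replicate 1 (0.040), and without WT 0 h replicate 1 (0.030), 0 h replicate 2 (0.045) or 3 h replicate 3 (0.043). MHC class II genes had positive mean terms, for example HLA-DOA (0.40 ± 0.07, 1.2e-06), from 8 and 12 h (0.573 and 0.589, against 0.0512 at 3 h). Among MHC class II genes 9 of 14 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.15 with an estimated correlation). The joint limma test of the 3 terms called 1858 genes (885 with a positive and 973 with a negative mean term), 2821 with the replicate number as a block, 1184 without WT 0 h replicate 2 and 1219 without KLHL6-KO 0 h replicate 2.

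Against WT tumours KLHL6 RNA did not follow the knockout labels, and NOTCH2 RNA was lower in NOTCH2-KO but not called in labelled DKO tumours. KLHL6 was higher in tumours labelled KLHL6-KO than in WT tumours (6536 ± 440.4 against 4372 ± 775, 0.59 ± 0.15, adjusted p = 0.013), a call lost without labelled KLHL6-KO replicate 3 (adjusted p = 0.066). It was also higher in NOTCH2-KO tumours (7433 ± 898, 0.77 ± 0.15, adjusted p = 0.0012) and not called in labelled DKO tumours (4574 ± 902, 0.06 ± 0.15, adjusted p = 0.83). NOTCH2 was lower in NOTCH2-KO tumours (356 ± 81.7 against 726 ± 267, -0.97 ± 0.21, adjusted p = 0.003), with WT replicate 1, at 420.2 counts, inside the NOTCH2-KO range. NOTCH2 was not called in labelled KLHL6-KO (466 ± 23.5, -0.56 ± 0.21, adjusted p = 0.08, but 1.1e-04 without WT replicate 1, 0.020 with DESeq2 and 0.038 with edgeR) or labelled DKO tumours (568 ± 41.1, -0.28 ± 0.21, adjusted p = 0.43, and 0.0041 without WT replicate 1). RNA level alone does not tell whether a frameshifted protein is made.

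**Figure D2:**
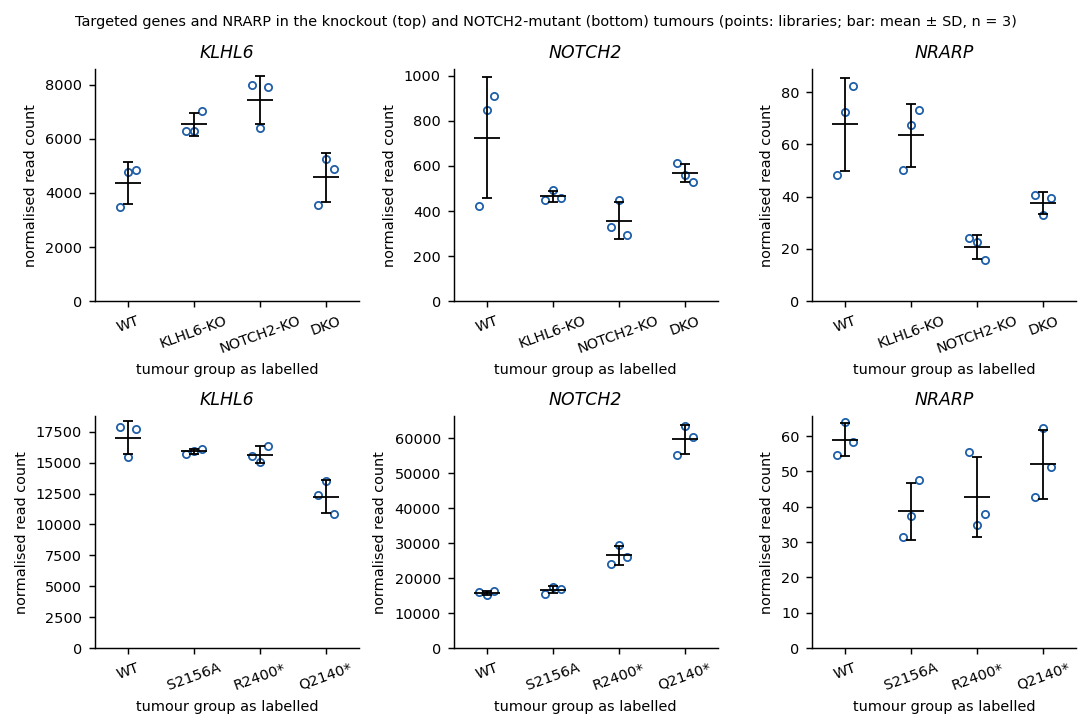
KLHL6, NOTCH2 and NRARP in each tumour library, knockout groups above and mutant groups underneath, with mean ± SD, n = 3 per group. NOTCH2 was at 726 ± 267 counts in WT and 356 ± 81.7 in NOTCH2-KO tumours, and at 15858 ± 567 in NOTCH2(WT) and 59619 ± 4181 in NOTCH2(Q2140*) tumours. The series were normalised separately.

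Tumours labelled KLHL6-KO nearly lacked a set of genes that WT tumours expressed. The synaptic adhesion gene NLGN4X (chromosome X, 5840637 to 6228863) was at 25.3 ± 1.64 against 630.2 ± 44.8 counts (-4.53 ± 0.14, adjusted p = 3.2e-12), with MEOX2 (-4.06 ± 0.20, 1.9e-09), YIPF6 (-3.78 ± 0.19, 1.9e-09) and BEX4 (-3.43 ± 0.36, 1.9e-05) lower as well. ABCA3 (4.16 ± 0.36, 2.1e-06), the adaptor SAMSN1 (2.46 ± 0.35, 2.6e-04), EGFR (2.19 ± 0.35, 7.5e-04) and BHLHE40 (2.11 ± 0.20, 5.7e-06) were higher. The NOTCH target CR2 (0.97 ± 0.16, 8.2e-04) was higher, and of the measured NOTCH targets 4 were higher and 2 lower (camera adjusted p = 0.59). Sterol genes were raised (8 of 21 higher and 0 lower, 11 and 0 adjusted over the list alone, adjusted p = 9.5e-06, adjusted p = 0.24 with an estimated correlation), interferon genes with OAS3 (0.77 ± 0.09, 5.4e-05) (5 of 15 higher and 0 lower, 6 and 0 adjusted over the list alone, adjusted p = 0.0016, adjusted p = 0.29 with an estimated correlation) and hypoxia genes with VEGFA (1.03 ± 0.16, 5.5e-04). Among hypoxia and glycolysis genes 7 of 21 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 2.8e-04, adjusted p = 0.79 with an estimated correlation). Limma called 2445 genes (1182 higher, 1263 lower), 1291 with the libraries of these groups alone, 1131 without labelled KLHL6-KO replicate 3 and 1416 without labelled KLHL6-KO replicate 1.

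NOTCH2-KO tumours had less of the NOTCH target NRARP than WT tumours (20.8 ± 4.53 against 67.6 ± 17.6, -1.60 ± 0.24, adjusted p = 1.5e-04), and less HEY1 (-1.45 ± 0.32, 0.0032) and IL2RA (-1.90 ± 0.44, 0.004), while the targets CR2 (1.19 ± 0.16, 6.9e-05) and DTX1 (0.61 ± 0.12, 0.0016) were higher (2 higher and 4 lower in the list, 3 and 4 adjusted over the list alone, camera adjusted p = 0.55). The pluripotency factor SOX2 (chromosome 3, 181711924 to 181714436) was at 248 ± 45.2 against 2.07 ± 1.44 counts (5.98 ± 0.43, adjusted p = 2.4e-07), with EPHA3 (5.33 ± 0.15, 4.6e-13) and the troponin TNNI1 (4.05 ± 0.34, 7.3e-07) also higher. Germinal-centre genes were higher, with SERPINA9 (1.38 ± 0.13, 2.9e-06) and MME (1.2 ± 0.11, 2.1e-06). Of 14 germinal-centre genes 8 were higher and 0 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.3 with an estimated correlation). Plasma-cell genes were higher, with CD27 (1.59 ± 0.13, 6.4e-07) and MZB1 (1.27 ± 0.14, 9.5e-06). Of 15 plasma-cell genes 10 were higher and 2 lower (12 and 3 adjusted over the list alone, camera adjusted p = 2.6e-04, adjusted p = 0.3 with an estimated correlation). BTK (0.91 ± 0.11, 2.4e-05) and CD79B (0.83 ± 0.12, 9.5e-05) of the B-cell receptor were higher. Among B-cell receptor genes 12 of 23 were higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.0067, adjusted p = 0.49 with an estimated correlation). The B-cell identity list was higher too. Among B-cell identity genes 14 of 20 were higher and 1 lower (15 and 2 adjusted over the list alone, camera adjusted p = 6.4e-05, adjusted p = 0.3 with an estimated correlation). CCL22 (-2.87 ± 0.28, 3.1e-06) and CCL3 (-1.55 ± 0.29, 0.001) were lower. Among NF-kB genes 2 of 21 were higher and 9 lower (2 and 11 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.39 with an estimated correlation). JUN (-1.43 ± 0.17, 2.1e-05) was lower too. Of 20 immediate-early genes 1 was higher and 8 lower (2 and 11 adjusted over the list alone, camera adjusted p = 0.0024, adjusted p = 0.3 with an estimated correlation). COL3A1 (2.47 ± 0.30, 3.0e-05) and the mean of the stroma list were higher beside these groups (5.48 ± 0.148 against 4.78 ± 0.0785 on the log2 scale), and that list call (5 of 13 higher and 0 lower, 7 and 1 adjusted over the list alone, adjusted p = 0.023, adjusted p = 0.3 with an estimated correlation) was lost without WT replicate 1 (adjusted p = 0.077). Limma called 4301 genes (2272 higher, 2029 lower), 297 and 465 of them by at least 2-fold.

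Labelled DKO tumours shared the lower chemokines and the higher EPHA3 with NOTCH2-KO tumours. CCL22 (-1.84 ± 0.28, 0.0015) and CCL3 (-1.86 ± 0.29, 0.0019) were lower, EPHA3 (2.67 ± 0.15, 3.5e-08) was higher and the long noncoding RNA LINC01391 was at 61.4 ± 15.2 against 0.26 ± 0.45 counts. SERPINA9 (0.76 ± 0.13, 0.0028) and TCF3 (0.54 ± 0.10, 0.0038) were higher. Interferon genes were raised with OAS1 (0.73 ± 0.11, 0.0015) and MX2 (0.74 ± 0.13, 0.0031) (7 of 15 higher and 0 lower, 9 and 0 adjusted over the list alone, adjusted p = 1.8e-04, adjusted p = 0.25 with an estimated correlation), as were sterol genes (3 of 21 higher and 0 lower, 5 and 0 adjusted over the list alone, adjusted p = 3.3e-04, adjusted p = 0.29 with an estimated correlation) and B-cell identity genes. Of 20 B-cell identity genes 6 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 8.7e-04, adjusted p = 0.55 with an estimated correlation). No NOTCH target was higher and 1 was lower (camera adjusted p = 0.76). The test called 1310 genes (770 higher, 540 lower), 231 with the libraries of these groups alone, 424 without labelled DKO replicate 3, the library of least depth, and 578 without labelled DKO replicate 2.

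Against tumours labelled KLHL6-KO, labelled DKO tumours expressed the genes missing there, with MEOX2 (5.23 ± 0.20, 4.6e-11), NLGN4X (4.92 ± 0.14, 8.5e-13) and YIPF6 (4.59 ± 0.19, 8.0e-11) higher, and had less SAMSN1 (-3.89 ± 0.35, 1.3e-06), ABCA3 (-3.16 ± 0.36, 2.2e-05) and EGFR (-2.34 ± 0.35, 3.7e-04). JUNB (-0.80 ± 0.10, 4.7e-05) and FOS (-1.58 ± 0.33, 0.0047) were lower. Among immediate-early genes 0 of 20 were higher and 9 lower (0 and 10 adjusted over the list alone, camera adjusted p = 2.0e-04, adjusted p = 0.46 with an estimated correlation). CD38 (0.88 ± 0.09, 4.6e-06) was higher. Among plasma-cell genes 5 of 15 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0048, adjusted p = 0.46 with an estimated correlation). The NOTCH target HES6 (0.76 ± 0.14, 0.0026) was higher (3 higher and 3 lower in the list, camera adjusted p = 0.24). The hypoxia gene ADM (-0.75 ± 0.10, 1.1e-04) was lower. Of 21 hypoxia and glycolysis genes 0 were higher and 3 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.0048, adjusted p = 0.49 with an estimated correlation). The mitochondrial share was 9.23 ± 0.649% against 7.35 ± 1.19%, with the mitochondrial list raised. Of 13 mitochondrially encoded genes 6 were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.46 with an estimated correlation). The test called 1508 genes (876 higher, 632 lower), and fewer without labelled KLHL6-KO replicate 1 (980), 2 (799) or 3 (901) or labelled DKO replicate 3 (879).

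Against NOTCH2-KO tumours, labelled DKO tumours lacked SOX2 (-5.77 ± 0.43, 2.1e-07) and SAMSN1 (-4.69 ± 0.35, 2.1e-07), and RGS18 was at 0.332 ± 0.575 against 134 ± 10.8 counts (-5.89 ± 0.34, adjusted p = 1.4e-08). PRDM1 (-1.11 ± 0.12, 1.2e-05), CD27 (-0.77 ± 0.13, 0.0014) and MZB1 (-0.74 ± 0.14, 0.0032) were lower. Of 15 plasma-cell genes 0 were higher and 8 lower (0 and 10 adjusted over the list alone, camera adjusted p = 2.3e-06, adjusted p = 0.29 with an estimated correlation). MX1 (1.45 ± 0.21, 4.1e-04) was higher and the NOTCH target CR2 (-0.78 ± 0.16, 0.0059) was lower (1 higher and 1 lower in the list, camera adjusted p = 0.71). KLHL6 was lower (-0.71 ± 0.15, adjusted p = 0.0075), a call lost without labelled DKO replicate 1 (adjusted p = 0.058). COL1A1 (-1.0 ± 0.21, 0.0067) and DCN (-1.52 ± 0.30, 0.0044) were lower beside them. Of 13 stroma genes 0 were higher and 6 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.29 with an estimated correlation). The test called 954 genes (493 higher, 461 lower), 1436 with the libraries of these groups alone, and fewer without labelled DKO replicate 1 (423) or 3 (470) or NOTCH2-KO replicate 1 (447), 2 (570) or 3 (460).

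The effect that goes with the KLHL6-KO label differed with NOTCH2 status. The interaction term, labelled DKO minus NOTCH2-KO less labelled KLHL6-KO minus WT, was -1.31 ± 0.21 for KLHL6 itself (adjusted p = 0.0011). For SAMSN1 (chromosome 21, 14485228 to 14658821) it was -7.16 ± 0.49 (adjusted p = 2.5e-07), with SOX2 (-5.29 ± 0.61, 5.0e-05), TNNI1 (-5.34 ± 0.48, 4.5e-06) and EPHA3 (-4.37 ± 0.21, 3.4e-09) also negative, and CTNND2 (5.36 ± 0.66, 1.1e-04) and MEOX2 (3.56 ± 0.28, 1.9e-06) positive. SERPINA9 (-2.05 ± 0.18, 4.8e-06) and CR2 (-1.75 ± 0.22, 1.5e-04) had negative terms, as had sterol genes (0 of 21 higher and 7 lower, 0 and 10 adjusted over the list alone, adjusted p = 1.2e-05, adjusted p = 0.26 with an estimated correlation) and VEGFA (-0.96 ± 0.22, 0.012) among hypoxia genes. Among hypoxia and glycolysis genes 0 of 21 were higher and 6 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.62 with an estimated correlation). The mitochondrial list had positive terms. Among mitochondrially encoded genes 5 of 13 were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 7.4e-04, adjusted p = 0.62 with an estimated correlation). The test called 1518 genes (774 positive, 744 negative), with 2410 without WT replicate 1 and fewer without NOTCH2-KO replicate 1 (760) or 3 (790), labelled DKO replicate 1 (822) or labelled KLHL6-KO replicate 1 (927) or 3 (837). Every list call in the knockout tumours was lost when the correlation within lists was estimated.

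**Figure D3:**
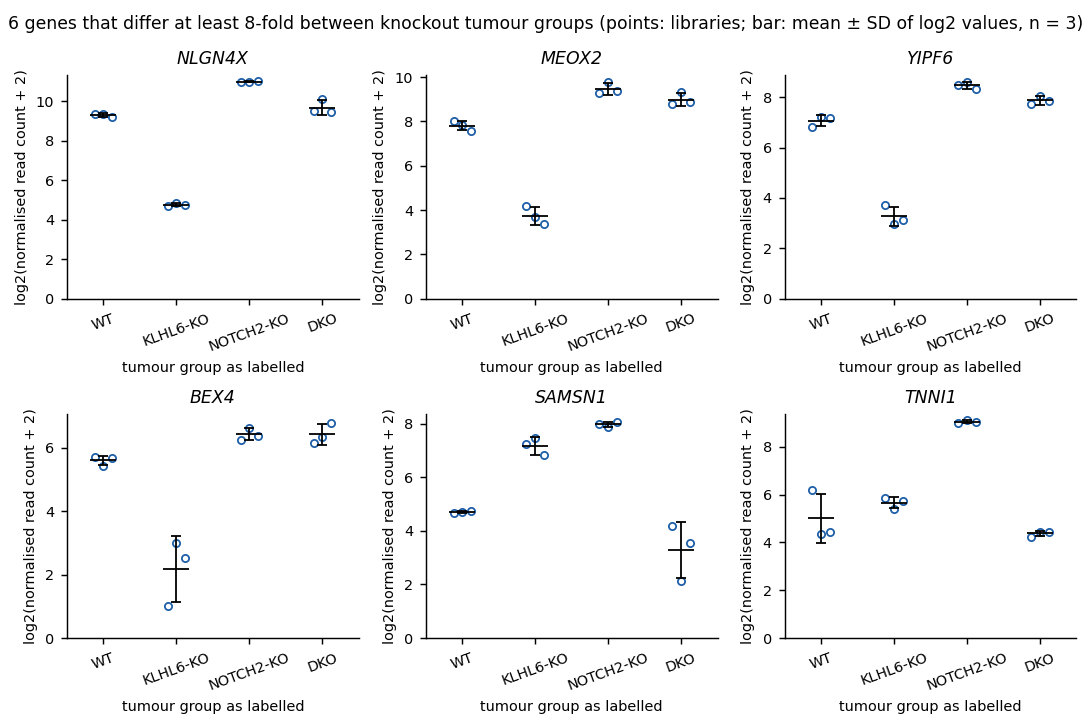
NLGN4X, MEOX2, YIPF6, BEX4, SAMSN1 and TNNI1 in the knockout tumours on the log2(count + 2) scale, points for libraries and lines for means, n = 3 per group. NLGN4X was at 25.3 ± 1.64 counts in labelled KLHL6-KO and 630.2 ± 44.8 in WT tumours.

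In the mutant tumours NOTCH2 RNA was highest where the receptor was truncated earliest. It was at 15858 ± 567 counts in NOTCH2(WT), 16650 ± 1050.4 in S2156A (0.07 ± 0.07, adjusted p = 0.59), 26466 ± 2748 in R2400* (0.73 ± 0.07, adjusted p = 7.8e-06) and 59619 ± 4181 in Q2140* tumours (1.91 ± 0.07, adjusted p = 2.1e-10). KLHL6 was lower in Q2140* tumours (12254 ± 1357 against 17014 ± 1356, -0.48 ± 0.07, adjusted p = 8.7e-05) and not called in S2156A (-0.09 ± 0.07, adjusted p = 0.43) and R2400* tumours (-0.12 ± 0.07, adjusted p = 0.36). The counts do not separate the introduced from the endogenous NOTCH2 transcript.

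S2156A tumours, in which a serine of the receptor is an alanine, had less of the NOTCH targets HEY2 (-0.79 ± 0.14, 2.0e-04), IL6R (-1.49 ± 0.15, 4.1e-08) and HES6 (-0.30 ± 0.07, 0.0052) and more CR2 (0.43 ± 0.08, 5.5e-04) than NOTCH2(WT) tumours (2 higher and 4 lower in the list, camera adjusted p = 0.65). The polarity scaffold MPDZ (chromosome 9, 13105704 to 13279590) was at 7.72 ± 2.64 against 212 ± 14.8 counts (-4.49 ± 0.43, adjusted p = 1.2e-05), with RUNX1T1 (-3.98 ± 0.44, 7.7e-07) and BEX4 (-3.82 ± 0.34, 3.6e-06) lower too. KSR1 (1.73 ± 0.12, 1.6e-10) and CELF2 (1.77 ± 0.16, 3.6e-06) were higher. No list was called with the filter on low values and all libraries of the mutants (camera). Without the filter plasma-cell (adjusted p = 0.0018), drug response (0.0076), B-cell receptor (0.019) and BCL2 family genes (0.027) were called. Plasma-cell genes (adjusted p = 0.058 with the filter) were also called with the libraries of these groups alone (0.013) and without NOTCH2(WT) replicate 1 (0.049) or 2 (0.022), and endothelium markers and mitochondrially encoded genes without NOTCH2(WT) replicate 1 (0.049 each). Limma called 2333 genes (1096 higher, 1237 lower), 118 and 209 of them by at least 2-fold, and 3914 with the libraries of these groups alone.

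R2400* tumours had lower RUNX1T1 (-2.76 ± 0.44, 2.6e-04), MPDZ (-2.68 ± 0.43, 0.002) and TNNI1 (-1.73 ± 0.25, 0.003) and higher SPN (1.38 ± 0.11, 2.1e-07). Of the NOTCH targets CR2 (0.45 ± 0.08, 7.7e-04) was higher and IL6R (-1.03 ± 0.15, 4.1e-05) lower (1 higher and 2 lower in the list, camera adjusted p = 0.99). Replication and mitosis genes were slightly lower, among them CCNA2 (-0.45 ± 0.06, 2.0e-05) and CENPF (-0.41 ± 0.05, 1.5e-06). Of 32 cell cycle genes 0 were higher and 4 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.0032, adjusted p = 0.87 with an estimated correlation). MT-ND4 (-0.40 ± 0.07, 0.0053) and the mitochondrial list were lower. Of 13 mitochondrially encoded genes 0 were higher and 3 lower (0 and 3 adjusted over the list alone, camera adjusted p = 9.7e-05, adjusted p = 0.87 with an estimated correlation). The test called 1235 genes (572 higher, 663 lower), 716 without NOTCH2(WT) replicate 1 and 758 without NOTCH2(WT) replicate 3.

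Q2140* tumours had less of the interleukin receptor chain IL2RB (-2.26 ± 0.17, 7.7e-08), of SAMSN1 (-2.28 ± 0.15, 3.7e-08) and of RUNX1T1 (-3.25 ± 0.44, 1.4e-05), and more of the platelet tubulin TUBB1 (3.04 ± 0.30, 1.0e-07) and of TCEAL9 (2.77 ± 0.21, 1.4e-09). The NOTCH target DTX1 (0.32 ± 0.05, 4.0e-05) was higher and HEY2 (-0.66 ± 0.14, 0.0013) lower (2 higher and 2 lower in the list, camera adjusted p = 0.99). Glycolytic genes were lower by small amounts, with GPI (-0.38 ± 0.04, 8.9e-07) and PGK1 (-0.37 ± 0.05, 3.5e-06). Of 21 hypoxia and glycolysis genes 0 were higher and 13 lower (0 and 18 adjusted over the list alone, camera adjusted p = 7.9e-10, adjusted p = 0.65 with an estimated correlation). HLA-DMB (0.74 ± 0.14, 3.5e-04) and CD74 (0.33 ± 0.06, 0.0019) were higher. Of 14 MHC class II genes 5 were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.65 with an estimated correlation). The stromal transcript SPARC (1.81 ± 0.21, 8.4e-07) was higher, the mean of the stroma list was 3.97 against 3.68, and the mitochondrial share was 6.94 ± 0.767% against 8.21 ± 0.311%, with its list lowered. Among mitochondrially encoded genes 0 of 13 were higher and 6 lower (0 and 8 adjusted over the list alone, camera adjusted p = 1.9e-04, adjusted p = 0.65 with an estimated correlation). The test called 3145 genes (1492 higher, 1653 lower), and 2063 without NOTCH2(WT) replicate 1.

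Between mutants, S2156A tumours differed from R2400* tumours in NOTCH2 itself (-0.67 ± 0.07, adjusted p = 3.9e-05), in the RNA-binding protein LIN28B (-2.42 ± 0.16, 1.7e-08) and in TCEAL9 (-1.95 ± 0.21, 2.5e-06), all lower, and in the endocytic receptor LRP2 (1.87 ± 0.14, 8.4e-09), which was higher, while the NOTCH target list was not called (camera adjusted p = 0.32). Compared with Q2140* tumours, S2156A tumours had more IL2RB (2.50 ± 0.17, 7.1e-09), SOCS3 (2.32 ± 0.18, 7.0e-07) and IL2RA (1.82 ± 0.24, 1.9e-04), less GAPT (-4.67 ± 0.31, 2.2e-11), HES6 (-0.47 ± 0.07, 1.9e-05) and DTX1 (-0.24 ± 0.05, 5.8e-04), and more GPI (0.47 ± 0.04, 9.9e-09) among glycolytic genes. Among hypoxia and glycolysis genes 15 of 21 were higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 5.9e-08, adjusted p = 0.56 with an estimated correlation). Q2140* tumours in turn had less SAMSN1 (-2.37 ± 0.15, 6.3e-08), IL2RB (-2.06 ± 0.17, 4.0e-07) and MYC (-0.45 ± 0.12, 0.0074) and more CD8A (1.90 ± 0.15, 1.1e-08) and IL6R (0.62 ± 0.15, 0.0038) than R2400* tumours, with replication genes such as MCM6 (0.49 ± 0.05, 1.7e-07) higher. Among cell cycle genes 9 of 32 were higher and 0 lower (11 and 1 adjusted over the list alone, camera adjusted p = 4.7e-04, adjusted p = 0.71 with an estimated correlation). Stromal SPARC (1.01 ± 0.21, 0.0013) was higher in Q2140* than in R2400* tumours as well. Among stroma genes 8 of 15 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 4.7e-04, adjusted p = 0.71 with an estimated correlation). The tests called 731 genes for S2156A against R2400* (296 higher, 435 lower, with 255 without R2400* replicate 1 and 304, 257 and 292 without S2156A replicate 1, 2 and 3), 4708 for S2156A against Q2140* (2338 and 2370) and 2908 for Q2140* against R2400* (1456 and 1452, and 1600 in total with the libraries of these groups alone).

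The changes of S2156A and R2400* against NOTCH2(WT) went together, with 375 genes higher in both (40.83 by chance), 466 lower in both (53.41 by chance) and 5 in opposite directions. Their log2 changes correlated with r = 0.678, against 0.497 in 50 simulations in which only the shared NOTCH2(WT) libraries linked them, with a covariance of 0.0708 against 0.0158. S2156A and Q2140* shared 239 higher genes (106.5 by chance) and 312 lower genes (133.2 by chance), with 220 opposite, and r = 0.221 lay under the simulated 0.498 while the covariance lay above its simulated value (0.0282 against 0.0158). R2400* and Q2140* shared 219 higher (55.58 by chance) and 303 lower genes (71.38 by chance), with 43 opposite, r = 0.440 against 0.498 and a covariance of 0.0421 against 0.0158.

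Effects in culture and in tumours had correlations near 0 across genes. The KLHL6-KO effect at 0 h and that in labelled KLHL6-KO tumours correlated with r = -0.0205. Over 21 pairs of a culture and a tumour comparison r ran from -0.134 to 0.0958, and in 19 of them it lay within 0.1 of 0. Within the tumours, the changes of NOTCH2-KO against WT and of labelled DKO against labelled KLHL6-KO tumours gave r = 0.305, with 430 genes higher in both (142.1 by chance) and 253 lower in both (91.56 by chance). Those of labelled KLHL6-KO against WT and of labelled DKO against NOTCH2-KO tumours gave r = 0.0700. The genes higher in WT cells at 3, 8 and 12 h of coculture, 2206 in number and 1891 measured in the knockout tumours, were lower in labelled DKO than in labelled KLHL6-KO tumours (44 higher, 122 lower, camera adjusted p = 0.011, adjusted p = 0.89 with an estimated correlation) and called in no other tumour comparison.

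**Figure D4:**
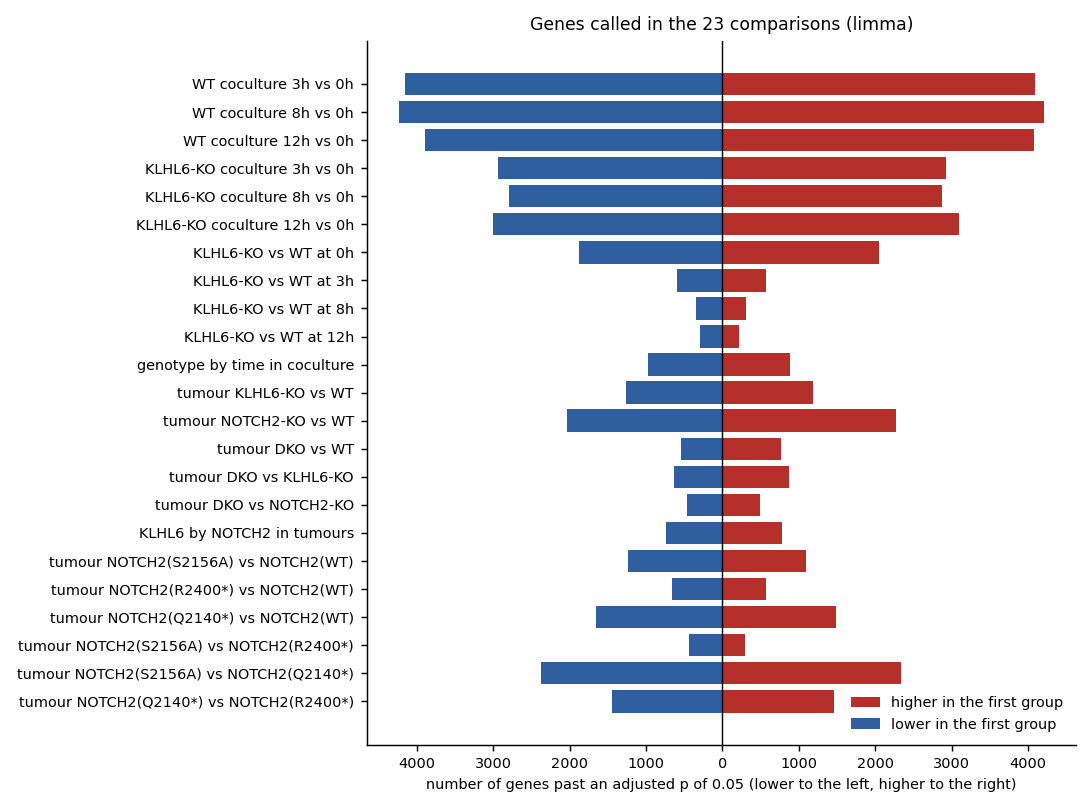
Genes called higher and lower in the 23 comparisons (limma, Benjamini-Hochberg adjusted p < 0.05), n = 3 libraries per group. The largest count was 8446 genes in WT cells at 8 h and the smallest 510 between KLHL6-KO and WT cells at 12 h.

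Targets of p53 (smallest adjusted p = 0.071) and the BCL2 family (0.11) were called in none of the 23 comparisons with the filter on low values and all libraries. Without the filter p53 targets were called in 6 of them, for example in WT cells at 3 h (adjusted p = 0.0095), and the BCL2 family in S2156A (0.027) and R2400* tumours (0.043). Targets of p53 were also called in labelled DKO against WT tumours without WT replicate 2 (0.042), and the BCL2 family in R2400* tumours without NOTCH2(WT) replicate 2 (0.045). The marker lists of macrophages (smallest adjusted p = 0.22), endothelium (0.092) and T and NK cells (0.075) were tested in the 12 tumour comparisons alone and called in none of them with all libraries. Endothelium markers were called in S2156A tumours without NOTCH2(WT) replicate 1 (0.049), and T and NK cell markers in labelled DKO against NOTCH2-KO tumours without labelled DKO replicate 3 (0.044) or NOTCH2-KO replicate 3 (0.025). Of 142 list calls in all comparisons 38 were kept with an estimated correlation, all of them in coculture.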

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

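The comparisons and the splits of libraries were chosen before the data were examined, as was the test for reads of mouse host cells. The tests of exchanged labels, of 1 shared KLHL6 effect and of sublines were chosen only after the result was seen.

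In coculture a difference between groups stood out: the change from 0 h on OP9-DLL1 differed between KLHL6-KO and WT cells for 1858 genes, among them EGR1 (mean term 1.57) and CD69 (1.74). Unequal levels of the genotypes at 0 h enter these terms. The difference itself was tested, as an interaction. Of 100 splits of the same libraries, 1, the real one, called as many genes, and the highest other called 1344. The splits drew genotype anew within each time, which breaks up the genotype effect along with the interaction. They therefore cannot decide whether chance accounts for the interaction count. The count was 2821 with the replicate number as a block and fell to 1184 without WT 0 h replicate 2 and to 1219 without KLHL6-KO 0 h replicate 2.

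In the knockout tumours the effect of the KLHL6-KO label differed with NOTCH2 status for 1518 genes, with terms of -1.31 for KLHL6 and -7.16 for SAMSN1. Of 100 splits 2, the real one included, called as many genes, and the highest other called 1988. Splits break up both edits' effects, so chance stays open. Leaving out 1 library, the count ran from 760 (NOTCH2-KO replicate 1) to 2410 (WT replicate 1).

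For the other 21 comparisons, of 3 libraries against 3, the 10 splits are too few for a share under 0.05. In each, 1 of the 10, the real one, called the most genes. Real and highest other counts were 8234 and 0 for WT cells at 3 h, 8446 and 0 at 8 h and 7963 and 0 at 12 h, and 5873 and 0, 5675 and 0, and 6089 and 0 for KLHL6-KO cells. For KLHL6-KO against WT they were 3927 and 673 at 0 h, 1175 and 0 at 3 h, 652 and 1 at 8 h, and 510 and 0 at 12 h. For the knockout tumours they were 2445 and 0 (labelled KLHL6-KO), 4301 and 0 (NOTCH2-KO) and 1310 and 1 (labelled DKO) against WT, and 1508 and 0 and 954 and 1 for labelled DKO against labelled KLHL6-KO and NOTCH2-KO. For the mutants they were 2333 and 0 (S2156A), 1235 and 0 (R2400*) and 3145 and 0 (Q2140*) against NOTCH2(WT), 731 and 0 (S2156A against R2400*), 4708 and 0 (S2156A against Q2140*) and 2908 and 1 (Q2140* against R2400*).

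KLHL6 RNA, lower in KLHL6-KO cells in culture, was not lower in tumours labelled KLHL6-KO. Exchanged WT and KLHL6-KO tumour labels, a candidate explanation, would turn the culture signature around. Genes lower in KLHL6-KO culture at all 4 times were higher in these tumours with the preset correlation (13 of 51 called higher and 3 lower, camera p = 0.0033), but with the estimated correlation p was 0.157, and genes higher in culture were not called (p = 0.415). The same genes were higher with camera at the preset correlation in NOTCH2-KO (camera p = 0.0062), labelled DKO (0.031), S2156A (8.4e-05) and R2400* tumours (7.3e-04), but in labelled DKO against NOTCH2-KO tumours, the other contrast of the KLHL6-KO label, they were lower as in culture (5 higher, 11 lower, camera p = 0.036, and 0.297 with the estimated correlation). The knockout rises share the WT tumours, so only the mutants show a rise beyond this label. KLHL6 goes with an exchange and NLGN4X, lower in culture too, against it, so it stays open. Whether the edit leaves the transcript in place was not tested.

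In the second pattern 41 genes, SAMSN1 among them, changed at least 8-fold between knockout tumour groups, several from near absence to abundance. In culture, without host cells, 56.1% of these genes (23 of 41) reached a value of 10 in at least 3 of the 6 libraries at 0 h. For these, mouse host reads are not the only source, but tumour levels and the other genes stay open. Genes that differ between sublines or clones of the line are a candidate explanation: 66.7% of the 33 measured in the mutant tumours were called there with at least 2-fold changes, against a median of 3.03% in 1000 random sets matched on mean expression, whose central 95% ended at 12.1%. For the 11 genes changed at least 8-fold in labelled KLHL6-KO tumours, 1 effect of the KLHL6 edit with and without NOTCH2 was undecided by calls. In labelled DKO against NOTCH2-KO tumours 4 were called in the same direction, 1 in the opposite and 6 in neither. The median log2 change was 3.43, against 0.56 in the same direction there (SD between genes 1.25), and the interaction was called for 10 of 11. The genes were chosen by the larger change, so this does not decide it either. The labels do not say whether clones or pools were edited, and an edit effect that depends on NOTCH2 was not told apart from sublines.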

How the results depend on the processing

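The tests with other pseudocounts, TMM scaling, edgeR with TMM as an alternative and the libraries that stood apart left out were chosen only after the result was seen.

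In the tumours replicate numbers do not pair the samples, while in coculture a structure shared by replicate number stays open. Deviations of same-numbered libraries correlated over 0.1 in 7 of 30 pairs in coculture, 3 of 15 in the knockout tumours and 0 of 18 in the mutants, with all pairs over 0.1 in 0 comparisons, and 16 of 24, 4 of 12 and 1 of 12 libraries correlated best with their own number. With the number as a block the count for KLHL6-KO against WT was 1814 at 3 h, 1027 at 8 h and 784 at 12 h, and 2821 for genotype by time. No other count moved over 1.5 times, and 8 list calls changed, among them NOTCH targets in genotype by time (adjusted p = 0.049).

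With the libraries of the compared groups alone, counts were 2074 for KLHL6-KO against WT at 3 h, 1291 for labelled KLHL6-KO and 231 for labelled DKO against WT tumours, 1436 for labelled DKO against NOTCH2-KO, 3914 for S2156A against NOTCH2(WT) and 1600 for Q2140* against R2400*. Fewer libraries estimate the variance there. DESeq2, edgeR, other pseudocounts, TMM scaling, no filter and leaving out the libraries that stood apart moved no count over 1.5 times.

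Leaving out 1 library at a time, the lowest and highest counts were 1184 (without WT 0 h replicate 2) and 2665 (WT 0 h replicate 3) for genotype by time. For KLHL6-KO against WT they were 647 (WT 3 h replicate 2) and 1035 (WT replicate 3) at 3 h, 381 (KLHL6-KO 8 h replicate 3) and 659 (WT replicate 3) at 8 h, and 282 (KLHL6-KO 12 h replicate 3) and 572 (WT replicate 2) at 12 h. For the tumours they were 1131 (labelled KLHL6-KO replicate 3) and 2776 (WT replicate 1) for labelled KLHL6-KO against WT, 424 (labelled DKO replicate 3) and 1591 (WT replicate 1) for labelled DKO against WT, 760 (NOTCH2-KO replicate 1) and 2410 (WT replicate 1) for KLHL6 by NOTCH2, 799 (labelled KLHL6-KO replicate 2) and 1287 (labelled DKO replicate 1) for labelled DKO against labelled KLHL6-KO, and 423 (labelled DKO replicate 1) and 1360 (labelled DKO replicate 2) against NOTCH2-KO. For the mutants they were 716 (NOTCH2(WT) replicate 1) and 1293 (R2400* replicate 3) for R2400*, 2063 (NOTCH2(WT) replicate 1) and 2957 (Q2140* replicate 3) for Q2140*, and 255 (R2400* replicate 1) and 1052 (R2400* replicate 2) for S2156A against R2400*. The cause of these shifts was not tested. Of 1009 calls of named genes 871 were kept in every such fit, and no named gene reversed direction.

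The mitochondrial list was not called at 12 h in KLHL6-KO against WT (adjusted p = 0.88) and was called in the opposite direction without WT 12 h replicate 1 (adjusted p = 1.9e-06), which is the 1 coculture library that stood apart, so leaving out the libraries that stood apart is the same fit. Over single libraries left out, its adjusted p ran from 1.9e-06 to 0.81 (without KLHL6-KO 12 h replicate 2). Without WT 12 h replicate 2 it was called in the direction of the full fit (3.7e-05). WT 12 h replicate 1 had a mitochondrial share of 23.2%, and leaving it out lowers the WT mean; the cause was not tested further. List calls lost with the compared groups alone were immediate-early (adjusted p = 0.096) and cell cycle genes (0.059) in WT cells at 3 h, stroma in WT cells at 12 h (0.17) and KLHL6-KO cells at 3 h (0.19), the NOTCH pathway in KLHL6-KO cells at 3 h (0.074), and B-cell receptor (0.052) and unfolded protein response genes (0.11) in KLHL6-KO against WT at 0 h, while 11 list results became called. TMM scaling lost the NOTCH pathway (0.075), and a pseudocount of 8 lost it (0.064) and stroma (0.064) in KLHL6-KO cells at 3 h. Without the libraries that stood apart, stroma (0.059) in NOTCH2-KO against WT and interferon genes (0.069) in labelled DKO against NOTCH2-KO tumours were lost, as was stroma in WT cells at 12 h (0.066), and 19 results became called. Without the filter, 48 list results that were not called became called and none was lost. With an estimated correlation the call of the coculture-raised genes in labelled DKO against labelled KLHL6-KO tumours was lost (adjusted p = 0.89).

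Among genes of at least 2 CPM correlations were -0.0562 (KLHL6-KO at 0 h and S2156A), 0.125 (labelled KLHL6-KO tumours and S2156A), 0.826 (WT and KLHL6-KO cells at 12 h), 0.0789 (WT at 12 h and R2400*) and 0.103 (KLHL6-KO at 12 h and R2400*). Leaving out 1 library, the correlation of WT and KLHL6-KO responses at 12 h ran from 0.769 (KLHL6-KO 0 h replicate 1) to 0.791 (WT 12 h replicate 2). Depth limits labelled DKO replicate 3 most, at 3.71 M reads.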

Other observations

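Beyond the groups already named, KLHL6-KO cells on OP9-DLL1 held more of the tumour necrosis factor receptor TNFRSF1B than WT cells (1.15 ± 0.17 at 3 h, 1.39 ± 0.17 at 8 h and 1.21 ± 0.17 at 12 h, all with limma adjusted p under 0.001) and less of the leukocyte integrin chain ITGB2 (-1.51 ± 0.18, -1.32 ± 0.18 and -1.18 ± 0.18).

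The tests of stroma reads, of RNA quality and of the 0 h resemblance were chosen only after the result was seen. VIM went from 1.59 ± 1.46 counts at 0 h to 77.7 ± 4.86 at 3 h in WT cells and from 0.326 ± 0.565 to 87.0 ± 23.2 in KLHL6-KO cells. Calls of the stroma list depended on the setting. In WT cells it was called at 3 h (adjusted p = 0.0094) and 8 h (0.031) without the filter on low values but not with it (0.21 and 0.15), and in KLHL6-KO cells at 3 h with a pseudocount of 2 (0.020) but not 8 (0.064). At 12 h in WT cells it was lost without replicate 1 (0.066), each call was lost with an estimated correlation, and between genotypes it was called at 0 h with the compared groups alone (0.020) and at 12 h without WT 12 h replicate 2 (0.026), but not with all libraries (0.13 and 0.44) or for genotype by time (0.22). RNA quality, read as the mitochondrial share, is argued against for the first 3 h in KLHL6-KO cells, where the share moved by -0.364 percentage points (pooled SD 0.553) while VIM rose. In WT cells it moved by 0.741 over that interval (pooled SD 0.709). The share was higher later, at 12.6 ± 0.928% at 8 h and 15.2 ± 2.5% at 12 h against 10.02 ± 0.347% at 0 h in KLHL6-KO cells and 16.2 ± 6.53% at 12 h against 9.64 ± 0.452% in WT cells, so RNA quality stays open for the later times and for WT cells. Reads of the OP9 stroma are a candidate explanation. Over the 18 cocultured libraries, with group means taken off, VIM and the mean of the stroma list correlated with Pearson r = 0.881 (permutation p = 1e-05, the smallest that 100000 resamples can give) and Spearman rho = 0.752 (permutation p = 5.8e-04), the 1 relation tested, and r was 0.676 without the 2 farthest libraries (WT 12 h replicates 1 and 2) and 0.564 over the 15 libraries without WT 12 h. Induction in the lymphoma cells was not tested.

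KLHL6-KO cells at 0 h resembled cocultured cells: the KLHL6-KO against WT change at 0 h correlated with the WT response at r = 0.59, 0.701 and 0.614 at 3, 8 and 12 h, a correlation that shares the WT 0 h libraries. With the KLHL6-KO response, where shared libraries push the correlation under 0, r was 0.236 at 3 h (jackknife SE 0.0734), 0.313 at 8 h and 0.169 at 12 h. The shared libraries therefore do not account for the sign. Genes are not independent replicates, and what makes the cells alike was not tested.

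Tumour WT replicate 1 stood apart from its group, with NOTCH2 at 420.2 counts against 850.3 and 908.6 in replicates 2 and 3. Of 26 of the 41 genes with 8-fold changes tested in culture, 2 were called with at least 2-fold changes in KLHL6-KO cells at 0 h.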
